A study of Homo sapiens with 8 samples.

How the data were processed

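Messenger RNA was measured in human dopaminergic neurons derived from induced pluripotent stem cells, a commercial product sold as iCell DopaNeurons. Per the labels, the neurons grew for 4 days on coated coverslips and received fresh medium a single time, on the day after plating. The coating was a nanostructure that mimics GDNF, the glial cell line-derived neurotrophic factor, or a scrambled form of it. The samples fall into the groups GDNF and CT, with 4 libraries each. The labels do not spell out CT, and the scrambled nanostructure is the only comparator the series names, so CT is read here as that comparator. The series design mentions 3 biological replicates per condition, whereas 4 numbered libraries per group were analysed here. All 8 samples carry the same treatment label of 10.73 mM, so no dose was compared. The labels do not say whether libraries came from separate cultures, and the p values measure only the spread between these samples, which may be technical.

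Per the labels, RNA was isolated from TRIzol extracts with a Monarch column kit, and polyA libraries were made with an Illumina TruSeq mRNA kit. The deposited values are raw read counts per Ensembl gene, whole numbers that were not normalized, in 1 column per library. Per the submitters' processing notes, FastQC, cutadapt, STAR, HTSeq and DESeq2 were used with the GRCh38 build. Tool versions, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Levels of genes with near-identical copies, overlapping genes or antisense partners are therefore uncertain. Overlaps of annotated exons were counted for the genes named by rule and the list members. Among those in the text not marked in place, VAMP2 (13.2% of its exonic bases) and CLU (2.28%) overlap a gene on the same strand. VIM (24.4%), GFAP (18.4%), HMGCS1 (14.95%), TUBA1A (14.3%), RPL15 (6.27%), UCHL1 (5.92%), LMX1A (4.18%), SLC17A6 (3.04%), GRIN2B (2.62%), RPL37A (2.27%), DCC (1.44%), FOXA1 (0.402%) and SLC1A2 (0.223%) overlap one on the other strand. ATF4 has 4 annotated pseudogenes named after it, TUBB3 2, and ATP5F1B, FOSL1, GJA1 and NDUFA4 1 each. The table lists 58395 genes, of which 17981 had no count in any library, and no line without a gene name. The 37 genes of the mitochondrial genome were listed with 0 counts in every library, so mitochondrially encoded mRNAs could not be compared. For 98.7% of the 58275 listed genes found in the GENCODE annotation used here, start and end positions were identical to it. That annotation gave GC content, length and exon overlap.

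Total counts ranged from 28698283 to 34559240 per library, at which depth a count of 0 allows up to 0.0868 to 0.105 CPM (3 counts per library, counting error only). Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 19999 genes holding 99.9% of the counts. The comparison was fitted with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM factors, robust dispersions, group as the only term and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. Levels are CPM, the usual depth-scaled counts, computed from the deposited counts with TMM-scaled library sizes, as mean ± SD over 4 libraries. Fold changes are log2 of GDNF over CT with 95% confidence intervals, and tests are two-sided. On simulated counts with the dispersions of these 8 libraries and 200 of 19999 genes changed, the test called 0% of genes changed 1.25-fold, 8% at 1.5-fold, 66% at 2-fold and 100% at 4-fold, with 1 false call. Simulated genes varied independently, without the trend with GC content described below. In the simulation 906 unchanged genes had an unadjusted p under 0.05, against 176 genes in the data. These rates therefore need not hold for the real comparison.

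The genes to be named, 39 gene lists, the design and the first set of alternatives were fixed before the data were examined. The rule named up to 12 genes per direction past the threshold with a mean of at least 5 CPM and groups that do not overlap. Where no gene passed, as here, it named the 10 smallest p values among genes of at least 5 CPM. It always named TH, SLC6A3, SLC18A2, DDC, NR4A2, RET, GFRA1, GFRA2, NCAM1, GDNF, MAP2 and TUBB3. IRF1 and the list members given as examples were chosen after their values were seen. Lists with at least 5 measured members, 36 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, fry and an exact permutation test of the list mean were run beside it. The smallest p that the exact test of 4 against 4 libraries allows is 0.0286. Adjusted over 36 lists, a list can pass it only if many lists reach that p together. Members were also adjusted over the list alone.

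The alternatives fixed beforehand were other scalings (DESeq2 size factors, upper quartile, totals), 2 other low-count filters, a replicate block, 1 surrogate variable (sva 3.50.0), leaving out each library, limma-voom with sample quality weights, DESeq2 1.42.0, a false discovery rate of 0.01, a test against a 1.5-fold change, and lists without shared members. Added after seeing the data were offsets for transcript GC content and length (mgcv 1.9.3, longest annotated transcript), the same with the block, leaving out CT replicate 2 and GDNF replicate 4 together, all 16 choices of 3 against 3 libraries, and the exact test of list means. Overlaps were counted with pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.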

Results

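The data set held 8 polyA RNA-seq libraries of human dopaminergic neurons, 4 from neurons on the GDNF mimic nanostructure (GDNF) and 4 from the comparator (CT), all taken on day 4. Total counts were 28698283 to 31692788 in CT and 29532090 to 34559240 in GDNF. The comparison asks which genes are expressed at a higher or lower level on the GDNF mimic than on its scrambled form.

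Neuronal and dopaminergic genes were expressed on both coatings, with group means close to each other, and no gene passed the test. Tyrosine hydroxylase (TH), the rate-limiting enzyme of dopamine synthesis, averaged 220 ± 74.8 CPM in CT and 219 ± 40.3 CPM in GDNF (n = 4 each). The GDNF receptor RET averaged 66.5 ± 13.1 and 64.7 ± 6.09 CPM, and its co-receptor GFRA1 227 ± 15.1 and 242 ± 8.59 CPM. Of 36 gene lists tested, 1 passed, that of the cytosolic ribosomal proteins, with a median log2 fold change of -0.15 (p = 0.244 with an estimated correlation). In edgeR, 0 of 19999 genes were higher and 0 lower in GDNF, and 176 genes had an unadjusted p under 0.05 (60 higher, 116 lower), where chance gives 1000. Among genes of at least 5 CPM the smallest edgeR p was 0.0323 and the 10th smallest 0.0492. Every gene with a p below 0.0323 thus averaged under 5 CPM. DESeq2 also called 0 genes (313 at an unadjusted p under 0.05), as did limma-voom with quality weights (837) and edgeR with 1 surrogate variable (443). Leaving out CT replicate 1 or CT replicate 2 moved the unadjusted count to 317 and 391, again with 0 genes past the threshold in edgeR. Among 11820 genes of at least 5 CPM, 48 (0.406%) had groups that did not overlap, where chance gives 2.86%. For 99.4% of these genes the 95% confidence interval of the fold change lay within 2-fold either way, and for 79.3% within 1.5-fold.

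Genes of dopamine synthesis and handling did not differ by more than the spread between replicates. TH (ENSG00000180176, chromosome 11, 2163929 to 2171877 in GRCh38) had a log2 fold change of -0.0041 (95% confidence interval -0.49 to 0.48). The closeness of its group means rests on CT replicate 2, at 325 CPM against 166 to 221 CPM in the other CT libraries. Without CT replicate 2 its log2 fold change was 0.25, and it did not pass. Dopa decarboxylase (DDC) averaged 336 ± 23.4 CPM in CT and 335 ± 20.01 CPM in GDNF, with an interval of -0.24 to 0.23, and 3.64% of its exonic bases lie antisense to another gene. The transcription factor NR4A2, needed for dopaminergic fate, averaged 121 ± 14.4 and 121 ± 10.1 CPM. The vesicular monoamine transporter SLC18A2 averaged 17.1 ± 3.23 and 17.9 ± 3.07 CPM, and 56.1% of its exonic bases lie antisense to other genes, so its level is uncertain. The dopamine transporter SLC6A3 was near the detection limit, at 0.431 ± 0.289 and 0.664 ± 0.285 CPM (log2 fold change 0.61, -0.47 to 1.69), and its fold change was 1.09 without CT replicate 1, 0.33 without CT replicate 4 and 0.32 without GDNF replicate 4. Of 23 measured genes of midbrain dopaminergic identity, 8 were higher and 15 lower in GDNF, and none passed over all genes or adjusted over the list alone. LMX1B averaged 828 ± 219 and 795 ± 80.0 CPM, LMX1A 329 ± 23.2 and 323 ± 16.4 CPM, and FOXA1 367 ± 14.6 and 371 ± 25.9 CPM. The list median was -0.0050, while camera placed the list higher (adjusted p = 0.946).

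**Figure D1:**
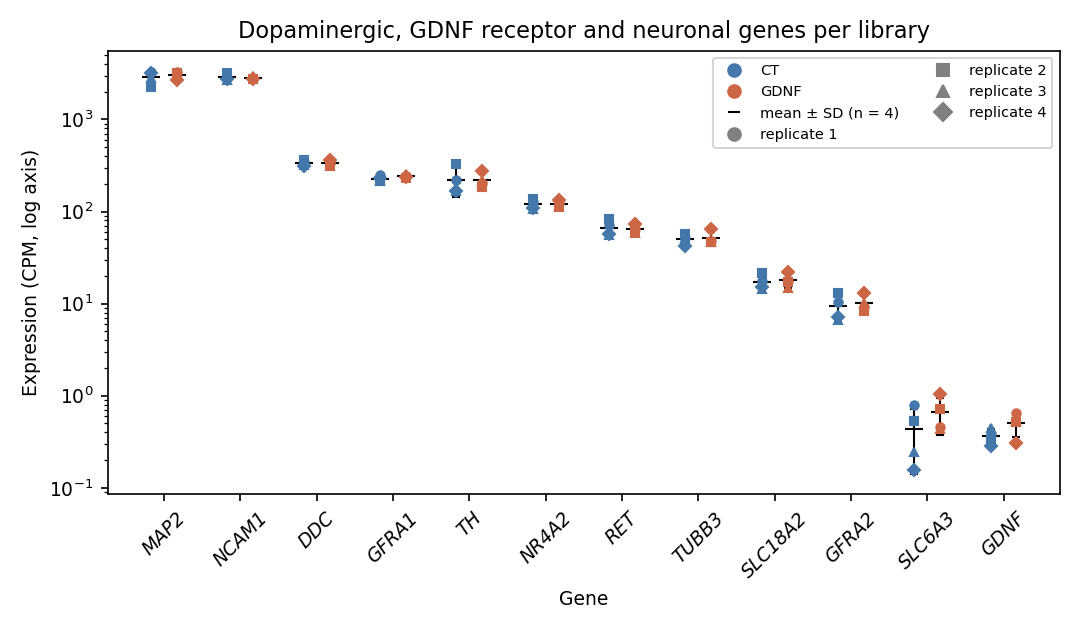
Expression in CPM (log axis) of the 12 genes fixed for every comparison, per library, with CT in blue, GDNF in orange, a marker shape per replicate and bars for the mean ± SD (n = 4). TH spans 166 to 325 CPM in CT and 184 to 277 CPM in GDNF, and the groups overlap for all 12 genes.

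The receptors and ligands of the GDNF family did not pass the test either. RET (ENSG00000165731, chromosome 10, 43077027 to 43130351) had a log2 fold change of -0.041 (-0.38 to 0.30), and GFRA1 (chromosome 10, 116056925 to 116273467) one of 0.09 (-0.14 to 0.32). GFRA2, the neurturin co-receptor, averaged 9.39 ± 3.03 and 10.2 ± 2.03 CPM, and NCAM1, an alternative GDNF receptor, 2860 ± 233 and 2803 ± 98.4 CPM, with 5.52% of its exonic bases antisense to other genes. GDNF itself was barely detected, at 0.361 ± 0.0706 and 0.503 ± 0.147 CPM (log2 fold change 0.48, -0.26 to 1.23), and 12.3% of its exonic bases lie antisense to another gene. Of the 20 measured members of the list, 8 were higher and 12 lower (camera adjusted p = 0.867). The artemin gene ARTN had the smallest p of the list, at 1.08 ± 0.322 CPM in CT and 0.630 ± 0.255 CPM in GDNF, and did not pass adjusted over the list alone.

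No list of signalling targets below the receptor passed its test. Of 20 targets and feedback regulators of ERK, 12 were higher and 8 lower, with a median of 0.011, whereas camera placed the list lower (adjusted p = 0.834). The ERK phosphatase DUSP4 averaged 730 ± 35.4 and 755 ± 59.6 CPM and the feedback inhibitor SPRY4 71.8 ± 8.12 and 72.7 ± 4.996 CPM. FOSL1 had the lowest p of that list, at only 0.551 ± 0.257 and 0.201 ± 0.00137 CPM, and did not pass adjusted over the list alone. Of 21 immediate early and activity-dependent genes 6 were higher and 15 lower (adjusted p = 0.359), with FOS at 51.7 ± 10.5 and 50.5 ± 6.35 CPM and VGF at 1675 ± 353 and 1678 ± 426 CPM. Of 21 neurotrophic factors and receptors 12 were higher and 9 lower (adjusted p = 0.433), with NTRK3 at 222 ± 25.6 and 230 ± 16.5 CPM.

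Neuronal structure and synapse genes were abundant and close between the groups. MAP2, a dendritic microtubule protein, averaged 2890 ± 478 and 3064 ± 255 CPM (log2 fold change 0.08, -0.21 to 0.38). The neuronal tubulin TUBB3 averaged 50.6 ± 6.34 and 51.2 ± 9.18 CPM, and 35.8% of its exonic bases are shared with another gene on the same strand. Of 29 axon and cytoskeleton genes 13 were higher and 16 lower (adjusted p = 0.834), with MAP1B at 10962 ± 1058 and 11568 ± 775 CPM. Of 34 axon guidance genes 19 were higher and 15 lower (0.401 for the adjusted p), with the netrin receptor DCC at 303 ± 41.3 and 320 ± 14.6 CPM. Of 30 presynaptic genes 15 were higher and 15 lower (adjusted p = 0.637), with VAMP2 at 592 ± 35.4 and 597 ± 43.8 CPM. Of 30 postsynaptic genes 20 were higher and 10 lower (adjusted p = 0.174), with GRIN2B at 303 ± 58.3 and 330 ± 25.2 CPM. Of 32 voltage-gated channel genes 21 were higher and 11 lower, with a median of 0.06 (adjusted p = 0.171) and SCN3B at 751 ± 39.6 and 791 ± 45.7 CPM. Neuropeptide genes split 9 higher and 13 lower (adjusted p = 0.834), and 20 Parkinson disease genes 9 higher and 11 lower (adjusted p = 0.972), with UCHL1 at 1217 ± 106 and 1157 ± 44.1 CPM. Without CT replicate 2, camera called the presynaptic genes (adjusted p = 0.0304, median 0.08) and the channel genes (adjusted p = 0.0157, median 0.08) higher at the preset correlation. Both calls were lost with an estimated correlation (adjusted p = 0.662 for each, unadjusted p = 0.142 and 0.119).

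The 10 genes of at least 5 CPM with the smallest p values were all lower in GDNF, by log2 values of -0.29 to -0.53 (p 0.0323 to 0.0492, adjusted p 0.9999), and none passed. COX6C (ENSG00000164919, chromosome 8, 99873200 to 99894062), NDUFA2 (ENSG00000131495, chromosome 5, 140638740 to 140647785) and NDUFB4 (ENSG00000065518, chromosome 3, 120596309 to 120602500) encode respiratory chain subunits. COX6C averaged 83.4 ± 7.62 and 68.1 ± 6.94 CPM, NDUFA2 27.0 ± 4.29 and 21.6 ± 0.768 CPM, and NDUFB4 56.3 ± 8.32 and 45.7 ± 2.71 CPM. Every CT library lay above every GDNF library for these 3 genes and for the pseudogene BTF3P13. Since the 10 genes were picked by their p values, this adds no support. PET100, a cytochrome oxidase assembly factor, averaged 7.34 ± 1.49 and 5.64 ± 0.635 CPM, and shares 12.8% of its exonic bases with a gene on the same strand. The others were IRF2, NMNAT3, TPPP3 and SERTAD3, at 5.41 to 8.53 CPM as group means, and the processed pseudogenes RPS19P1 and BTF3P13. How far reads of these pseudogenes can be told from those of their parent genes was not measured, so their levels are uncertain. Without CT replicate 2 the log2 fold changes were smaller, at -0.20 for NDUFA2, -0.23 for PET100, -0.25 for SERTAD3 and -0.35 for TPPP3. With limma-voom they were smaller for NDUFB4 (-0.13), COX6C (-0.17), BTF3P13 (-0.26) and SERTAD3 (-0.28), as was RPS19P1 with the GC and length offsets (-0.25), under which the intervals of COX6C (-0.86 to 0.011) and NDUFB4 (-0.93 to 0.048) included 0. The offsets made the fold changes of COX6C (-0.42), NDUFB4 (-0.44), NMNAT3 (-0.48), BTF3P13 (-0.46) and IRF2 (-0.43) larger. Those of NDUFA2 (-0.26), TPPP3 (-0.44), PET100 (-0.28) and SERTAD3 (-0.31) became smaller. NDUFA2 has antisense partners over 13.04% of its exonic bases and SERTAD3 over 8.57%, and TPPP3 shares 6.11% and NMNAT3 2.16% with a gene on the same strand, so these levels are uncertain. COX6C and NDUFB4 have 17 and 12 annotated pseudogenes named after them.

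**Figure D2:**
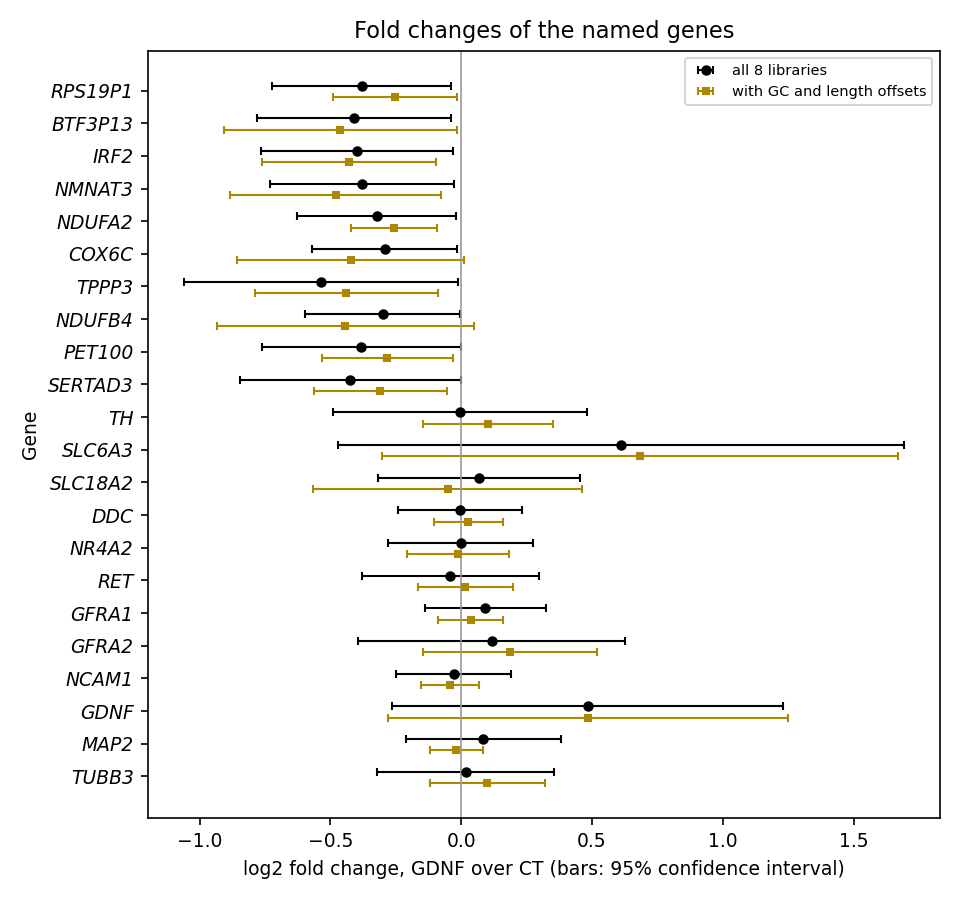
Log2 fold change of GDNF over CT with its 95% confidence interval for the 22 named genes, in black for all 8 libraries and in yellow with offsets for GC content and length. TH lies at -0.0041 in the former and at 0.10 (-0.15 to 0.35) in the latter, and no gene passed the test in either.

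Cytosolic ribosomal protein genes were the only list past the threshold, and were lower in GDNF. Of 37 measured members 32 were lower and 5 higher, with a median of -0.15 (interquartile range -0.19 to -0.09) and a camera adjusted p of 1.72e-04; p = 0.244 with an estimated correlation. All 37 members have annotated pseudogenes named after them, 279 in total, of which the 59 that were measured held 11.1% as many CPM as the members, so the levels of these genes are uncertain. RPL37A averaged 310 ± 46.8 and 266 ± 15.7 CPM and RPL15 372 ± 75.9 and 374 ± 36.5 CPM. No member had an unadjusted p under 0.05 in edgeR, and the exact permutation test of the list mean gave p = 0.314. Fry gave p = 0.306, and 0 lists passed with fry, the estimated correlation or the exact test. For the exact test this carries little weight, since its smallest possible p nearly fixed the outcome in advance. The call was lost without CT replicate 2 (median -0.051, adjusted p = 0.191), without CT replicate 3 (-0.12, adjusted p = 0.487) and without GDNF replicate 2 (-0.10, adjusted p = 0.0642), over a range of adjusted p from 5.34e-06 to 0.900 over these tests and alternatives, and up to 0.981 where an estimated correlation was combined with another setting. The number of lists called was 5 without CT replicate 2, 0 without CT replicate 3 and 0 without GDNF replicate 2.

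**Figure D3:**
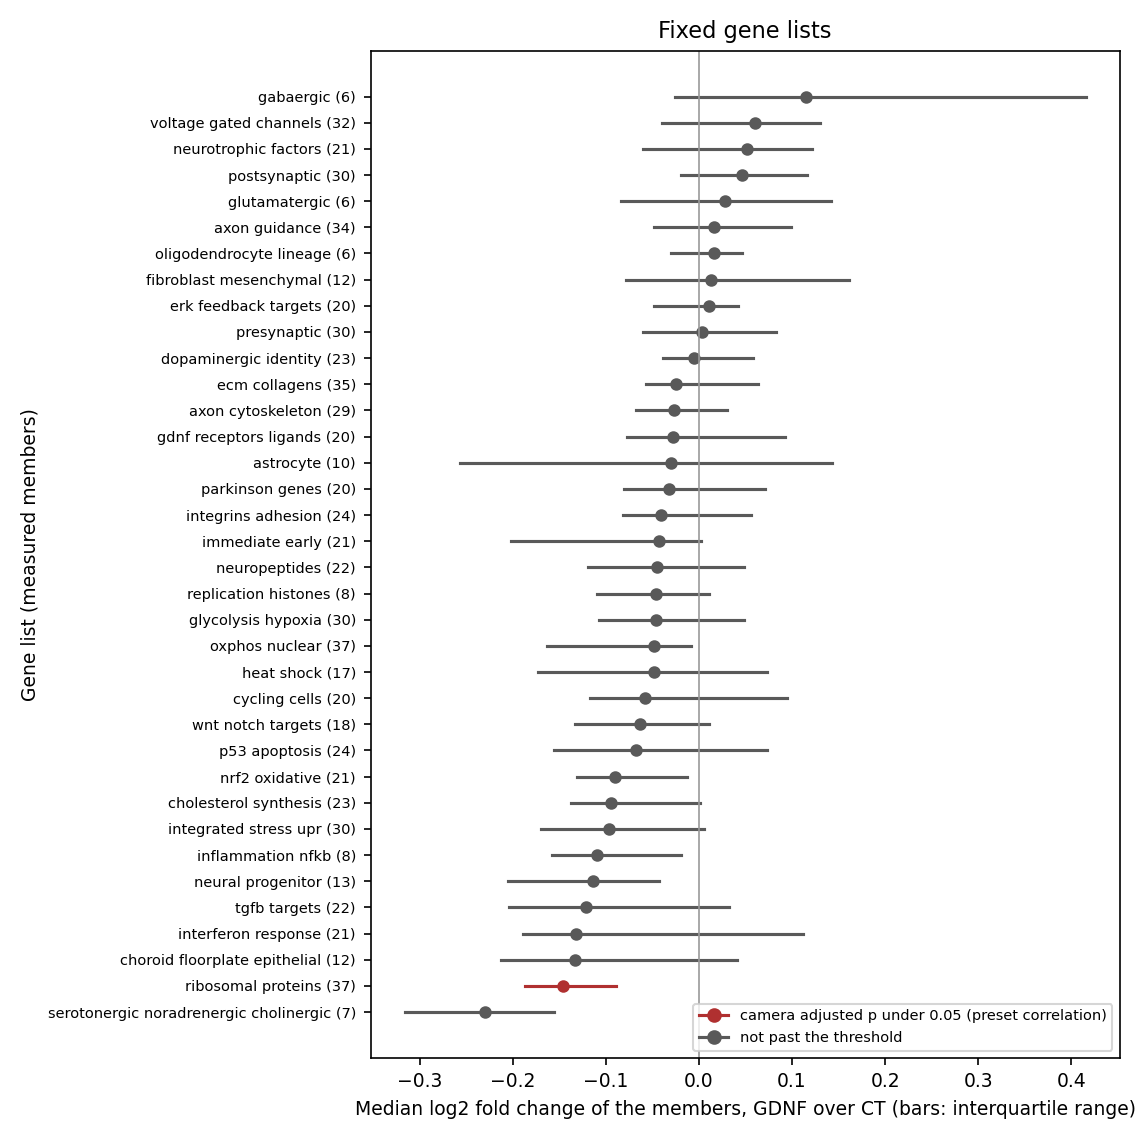
Median log2 fold change of GDNF over CT of the measured members of each tested list, with the interquartile range as bars and the number of members in parentheses. The ribosomal proteins, in red, lie at -0.15, and the medians of all lists run from -0.23 to 0.11.

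The lists of respiratory chain, glycolysis and sterol synthesis genes did not pass the test. Of 37 nuclear-encoded respiratory chain genes 28 were lower and 9 higher, with a median of -0.048 (adjusted p = 0.171), and ATP5F1B stood at 641 ± 62.6 and 630 ± 53.5 CPM. Of 30 glycolysis and hypoxia genes 20 were lower (adjusted p = 0.562), with ENO2 at 824 ± 141 and 780 ± 57.8 CPM. Of 23 sterol synthesis genes 17 were lower (adjusted p = 0.179), with HMGCS1 at 798 ± 300 and 847 ± 48.7 CPM. Without CT replicate 2 the respiratory chain list was called lower (median -0.06, adjusted p = 0.0157), and this call was lost with an estimated correlation (adjusted p = 0.662).

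Stress and inflammatory genes did not pass as lists either. Of 30 targets of ATF4 and the unfolded protein response 22 were lower (adjusted p = 0.174), with ATF4 at 250 ± 41.1 and 218 ± 15.6 CPM. NRF2 and antioxidant genes counted 16 of 21 lower (adjusted p = 0.179), p53 and cell death genes 15 of 24 (adjusted p = 0.438), heat shock genes 9 of 17 (adjusted p = 0.593), and NF-kB targets 6 of 8 (adjusted p = 0.171). Of 21 interferon-stimulated genes 12 were lower and 9 higher (adjusted p = 0.334). The interferon-induced transcription factor IRF1 (chromosome 5, 132481609 to 132490798) averaged 1.34 ± 0.268 and 0.687 ± 0.0324 CPM, a log2 fold change of -0.96 (-1.48 to -0.44). It was the 1 gene of 729 distinct list members that passed adjusted over the list alone (0.0395), and it did not pass over all genes (adjusted p = 0.9999). Leaving out CT replicate 2, 3 or 4 or any 1 of the 4 GDNF replicates left 0 members that passed adjusted over the list alone. IRF1 was chosen after its values were seen, 22.0% of its exonic bases lie antisense to other genes, and 11 of the 729 members had an unadjusted p under 0.05.

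Matrix, adhesion and developmental signalling genes showed no list past the threshold. Of 35 matrix genes 14 were higher and 21 lower, with a median of -0.025, while camera placed the list higher (adjusted p = 0.468), and COL6A1 stood at 328 ± 98.5 and 316 ± 28.8 CPM. Without CT replicate 2 the matrix list was called higher (median 0.10, adjusted p = 0.0157), and this call was lost with an estimated correlation (adjusted p = 0.662). Integrin and adhesion genes counted 15 of 24 lower (adjusted p = 0.900), TGF-beta and YAP targets 15 of 22 (adjusted p = 0.171), and Wnt and Notch targets 12 of 18 (adjusted p = 0.196).

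Of the lists of other cell types 9 were tested and none passed in camera (smallest adjusted p 0.171). Cell cycle genes counted 13 of 20 lower with a median of -0.06, while camera placed the list higher (adjusted p = 0.657), and TOP2A averaged 0.967 ± 0.546 and 1.75 ± 0.420 CPM without passing. Progenitor genes counted 10 of 13 lower (adjusted p = 0.196), with VIM at 315 ± 45.7 and 305 ± 44.4 CPM. Astrocyte genes split 5 and 5 (adjusted p = 0.732), with GFAP at 0.451 and 0.340 CPM as group means. Oligodendrocyte genes counted 4 of 6 higher with a median of 0.016, while camera placed them lower (adjusted p = 0.637), and fibroblast genes split 6 and 6 (adjusted p = 0.637). Epithelial, choroid and floor plate genes counted 8 of 12 lower (adjusted p = 0.359). GABAergic genes counted 4 of 6 higher with a median of 0.11 (adjusted p = 0.171), glutamatergic genes 4 of 6 higher (adjusted p = 0.593), and serotonergic, noradrenergic and cholinergic genes 6 of 7 lower (adjusted p = 0.171). SLC17A6, the vesicular glutamate transporter, averaged 111 ± 22.0 and 114 ± 12.9 CPM. The GABAergic list was called higher without CT replicate 2 (median 0.26, adjusted p = 0.00896), and this call was lost with an estimated correlation (adjusted p = 0.486, unadjusted p = 0.0131). Pluripotency and microglial or endothelial lists had 4 measured members each and were not tested, with medians of -0.0018 and -0.0068. Replication histone genes counted 6 of 8 lower with a median of -0.046, while camera placed them higher (adjusted p = 0.949).

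CT replicate 2 stood apart from the other 7 libraries. Its genes deviated from the other libraries with the GC content of the transcript (Spearman correlation 0.910 across genes, which are not independent replicates), with median log2 deviations of -0.96 in the lowest and 0.60 in the highest GC quartile. Its correlation of log CPM with the other libraries had a median of 0.962, and the lowest of any pair without it was 0.985. GDNF replicate 4 had the next highest GC correlation, 0.858. With offsets for GC content and length, chosen after this was seen, edgeR called 0 genes (338 at an unadjusted p under 0.05), and the interval lay within 1.5-fold for 97.2% of genes of at least 5 CPM.

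**Figure D4:**
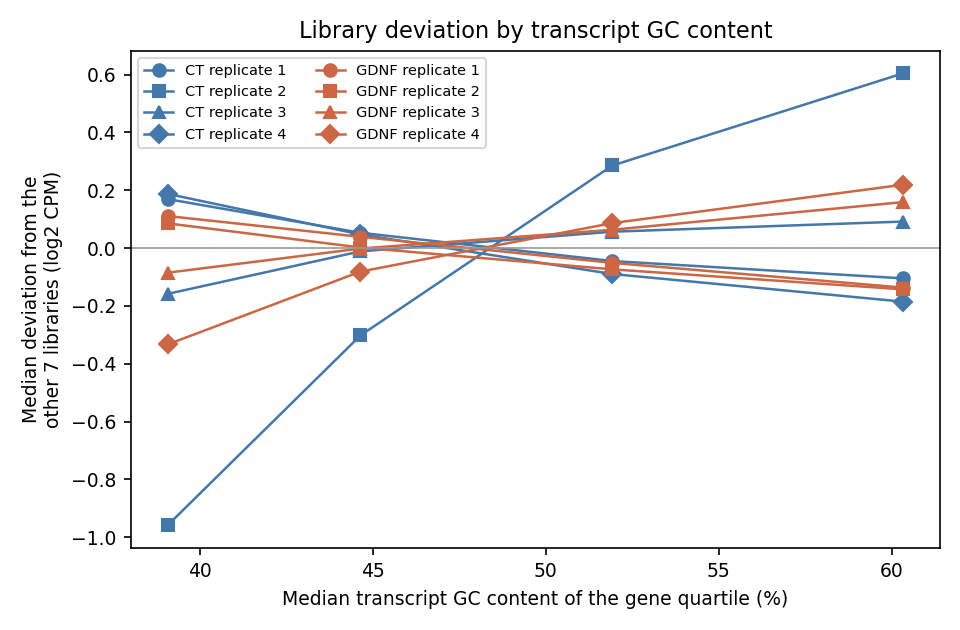
Median log2 deviation of each library from the other 7 by quartile of transcript GC content (percent), with CT in blue, GDNF in orange and a marker shape per replicate. CT replicate 2 runs from -0.96 to 0.60, and GDNF replicate 4 from -0.33 to 0.22.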

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

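In this part the tests of sequencing depth and of summed marker levels were chosen only after the result was seen.

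In 6 of 132 groups of 4 values 1 library lay far from the others, where chance gives about 1 in 20, or 7. CT replicate 2 accounts for 3 of them. Its deviations from the other libraries had an SD of 0.68 (log2), against 0.18 to 0.21 in the other CT libraries. Its median correlation with the other libraries was 0.962, against 0.988 to 0.989. COX6C stood at 94.8 CPM in it, against 79.2 to 80.3 CPM in the other CT libraries, all above the highest GDNF library at 75.5 CPM. TUBB3 stood at 65.0 CPM in GDNF replicate 4, against 46.2 to 47.6 CPM. The mean log2 CPM of the dopaminergic identity list was 5.83 in GDNF replicate 4, against 5.58 to 5.63. The mean log2 CPM of the TGF-beta and YAP target list was 2.57 in GDNF replicate 3, against 2.43 to 2.45.

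The distance of CT replicate 2 from the other 7 libraries was weighed against 3 explanations, and no biological explanation beyond another cell type was tested. Its depth argues against a depth effect, since its total count of 31251748 lay inside the range of the others. A GC content bias of this library is a candidate explanation, since within 30 lists of unrelated function its deviation followed transcript GC content, with a median Spearman correlation of 0.854 and a lowest of 0.539. The lists repeat the correlation of 0.910 across genes, so they do not tell this bias from another cause that follows GC content. After correction for GC content and length CT replicate 2 still stood apart. Its deviations then had an SD of 0.30 (log2), against 0.10 to 0.18 in the other libraries. Another cell type of the 11 lists is argued against as the cause: the median fall of -0.96 in the lowest GC quartile would need at least 48.5% of the RNA to come from other cells, yet no list's summed markers lay above 1.44 times the median of the other libraries, and after correction for GC content and length the highest list median was 0.35 (log2), below the bound of 0.5 set beforehand. That highest median was in the astrocyte list, with 8 of 10 members above 0. The interval up to 1.03 rests on SLC1A3 (0.632 against 0.400 CPM) and SPARCL1 (0.765 against 0.519 CPM). In CPM, which is not corrected, SLC1A2 stood at 151 against 313, GJA1 at 1.30 against 2.07 and AQP4 at 0.898 against 1.18. CLU stood at 244 against 176 and GFAP at 0.499 against 0.439, and the members not named here were also higher in CT replicate 2. After correction only SLC1A2 (-0.41) and GFAP (-0.21) lay below 0.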

How the results depend on the processing

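The GC and length offsets, the joint removal of CT replicate 2 and GDNF replicate 4, the 3 against 3 choices and the exact test of list means were chosen only after the result was seen. Under all 53 alternatives 0 genes passed in edgeR, DESeq2 or limma-voom. Genes at an unadjusted p under 0.05 numbered 20 to 1024 against 176, with 118 to 391 when 1 library was left out, 113 to 510 (edgeR) and 128 to 416 (DESeq2) with 3 against 3 libraries, 1024 without a low-count filter, 80 with the CPM filter, 443 with a surrogate variable, 837 with limma-voom, 313 with DESeq2, 20 against a 1.5-fold change, 338 with the offsets and 320 with the offsets and the block. The cause was not tested, apart from the changes in genes or samples tested.

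With the replicate number as a block 0 genes passed (112 at an unadjusted p under 0.05), 1 list was called (ribosomal median -0.12) and 0 members passed adjusted over the list alone. The values did not show that the numbers pair the samples: 2 of 8 libraries correlated best with the library of their own number, and the same-number correlations of deviations were 0.273, -0.315, 0.173 and -0.419 for numbers 1 to 4. After correction for GC content and length, in the more abundant genes, they were 0.328, -0.204, 0.448 and -0.456. Structure linked to a number is therefore not excluded. The block changed no other call.

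Against 1 list called, 0 were called without a low-count filter (ribosomal median -0.13, adjusted p = 0.0738) and with the estimated correlation, fry and the exact test (median -0.15), 4 with 1 surrogate variable, 5 with limma-voom, 5 without CT replicate 2 and GDNF replicate 4, and 0 to 5 when 1 library was left out. The outcome of the exact test was nearly fixed in advance by its smallest possible p. With a surrogate variable, limma-voom and the joint removal of CT replicate 2 and GDNF replicate 4, in that order, camera called channels (adjusted p = 0.0360, 0.0162 and 0.0155) and GABAergic genes (0.0360, 0.00917 and 0.0155) higher, and the respiratory chain (0.0360, 0.0162 and 0.00204) and ribosomal genes (0.00277, 0.00917 and 0.00542) lower. Sterol synthesis was called lower with limma-voom (0.0283) and the joint removal (0.00204). Of 32 list calls over all settings where an estimated correlation was also run, 0 held with it (adjusted p = 0.367 to 0.981). For the GABAergic list camera with an estimated correlation gave unadjusted p values of 0.0319 with the surrogate variable, 0.0102 with limma-voom and 0.0344 with the joint removal. The ribosomal median ran from -0.21 to -0.051 over the alternatives that can move it. The cause was not tested.

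Among the values of single named genes under an alternative, 397 kept their direction and 61 reversed, all at small fold changes that passed in no setting. When 1 library was left out, the log2 fold change of TH ran from -0.13 to 0.25, DDC from -0.035 to 0.041, NR4A2 from -0.055 to 0.073, RET from -0.12 to 0.092, NCAM1 from -0.064 to 0.033, MAP2 from -0.011 to 0.15, SLC18A2 from -0.043 to 0.20, GFRA2 from -0.017 to 0.33 and TUBB3 from -0.11 to 0.089. TH was 0.15 with a surrogate variable, 0.0074 with DESeq2, 0.0015 with its size factors, 0.10 with the offsets, 0.12 with offsets and block, 0.011 with totals, 0.089 with limma-voom, 0.0083 without a filter, 0.038 with the block and 0.12 without CT replicate 2 and GDNF replicate 4. DDC was 0.018 with a surrogate variable, 0.0035 with DESeq2, 0.028 with the offsets and 0.028 with the block too, 0.0054 with totals, 0.022 with limma-voom, 0.0073 without a filter and 0.0026 without the 2 libraries. NR4A2 was 0.036 with a surrogate variable, 0.0072 with DESeq2, 0.0020 with its size factors, 0.0096 with totals, 0.032 with limma-voom, 0.010 without a filter, 0.0020 with the block and 0.020 without the 2 libraries. RET was 0.030 with a surrogate variable, 0.016 with the offsets, 0.019 with offsets and block, 0.032 with limma-voom and 0.026 without the 2 libraries. MAP2 was -0.018 and SLC18A2 -0.051 with the offsets, and -0.018 and -0.012 with offsets and block. NCAM1 was 0.0038 with limma-voom and 0.044 without the 2 libraries, and TUBB3 -0.0054 with the upper quartile and -0.050 without the 2 libraries. The cause was not tested. GDNF and SLC6A3 have no value with the CPM filter, which removed them. IRF1 stayed at -0.81 to -1.06. Members passing adjusted over the list alone numbered 4 with a surrogate variable (IRF1, NDUFA2, COX6C and NDUFA4) and 0 without a low-count filter, with DESeq2 and with the offsets.

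Depth limits the genes near the detection limit, such as SLC6A3 and GDNF. The spread between libraries limits the rest: with the dispersions left after the offsets, simulated counts gave 84% recovery at 1.5-fold and 100% at 2-fold, with 7 false calls. Simulated genes again varied independently, and 935 unchanged genes had an unadjusted p under 0.05, against 338 genes in the data with the offsets. These rates too need not hold for the real comparison.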

Other observations

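In this part the test of the ribosomal list against a GC and length trend, with its reading by an estimated correlation, was chosen only after the result was seen. For the test of detained introns, the interval around the median was added after the values were seen, and the median of CT replicate 3 alone met the bound written down beforehand as counting against that explanation.

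Among nuclear genes, by CPM not scaled to transcript length, the highest mean was that of PEG10, an imprinted gene derived from a retrotransposon, at 15634 ± 1544 CPM in CT and 16925 ± 641 CPM in GDNF. MAP1B came next, followed by actin ACTG1 (5389 ± 1033 and 4999 ± 588 CPM), tubulin TUBA1A (5139 ± 594 and 5015 ± 480 CPM), actin ACTB (4877 ± 826 and 4638 ± 592 CPM) and the G protein subunit GNAS (3737 ± 453 and 3520 ± 129 CPM). Single libraries varied far more in some nuclear RNAs than the groups did: MALAT1 stood at 396 CPM in CT replicate 2, 566 in CT replicate 1, 1322 in CT replicate 3 and 1410 in CT replicate 4, and at 613 to 818 CPM in GDNF. ALDH1A1, a marker of a subset of midbrain dopaminergic neurons, had 43 counts over all 8 libraries.

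Of the 35 splits of the 8 libraries into 4 and 4, 22 called as many lists as the real split, which called 1 (highest other 6), so chance cannot be excluded for that count. The real split called 0 genes in edgeR (176 at an unadjusted p under 0.05; 313 with DESeq2 and 837 with limma-voom), which all 35 splits reach by construction, so that count says nothing about chance. At an unadjusted p under 0.05, 33 of the 35 splits gave at least 176 genes. The highest other split called 734 genes, with CT replicates 1 and 4 and GDNF replicates 1 and 2 on one side and the remaining 4 libraries on the other. The former 4 deviated from the other libraries with GC content at Spearman correlations of -0.79 to -0.60 and the latter 4 at 0.47 to 0.91, so the count points to a structure of the samples that follows the sign of that correlation and crosses the groups.

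For the lower ribosomal protein genes in GDNF, chance cannot be excluded either, since 8 of the 35 splits gave a camera p as small as the real 4.79e-06 (smallest other 1.29e-08). With offsets for GC content and length the median was -0.086 against -0.15, and camera called the list at the preset correlation (adjusted p = 0.00110) but not with an estimated correlation (adjusted p = 0.924). Without the offsets the list had not passed with an estimated correlation either (adjusted p = 0.649), so that result does not bear on the trend. By the rule written for this test, the call at the preset correlation counts against the trend as the whole cause. After the offsets, however, 9 of the 35 splits gave a camera p as small as the real one. The remaining call may thus itself be chance, and the trend stays open. Without CT replicate 2 the median was -0.051, between the bounds set for a cause in that library alone and against it. An effect of the nanostructure stays open and was not tested apart from these.

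CT replicate 3 and GDNF replicate 3 lay together on the component that carried 22.9% of the variance after correction for GC content and length, at 9.83 and 13.4, with the other libraries at -7.56 to -1.55. A gain of another cell type of the 11 lists was argued against: the highest list reached a median deviation of only 0.068 (log2) in the lower of both libraries. No upper bound of a list median in either library was above 0.45. A smaller share of such cells in these libraries was not tested. Less intron-retaining nuclear RNA in these libraries may play a part: after this correction 22 genes known for detained introns had a median of -0.074 in CT replicate 3 (interval -0.23 to -0.022, 18 below 0) and -0.31 in GDNF replicate 3 (interval -0.38 to -0.10, 21 below 0), against -0.017 to 0.08 in the other libraries. Without the correction the medians were -0.18 in CT replicate 3 and -0.37 in GDNF replicate 3, but also -0.52 in CT replicate 2 and -0.18 in GDNF replicate 4. The contrast with all other libraries therefore appeared only after correction. Of 2 single nuclear RNAs in uncorrected CPM, MALAT1 went against this explanation in CT replicate 3. It stood there at 1322 CPM, above every library but CT replicate 4 (1410 CPM), and at 665 CPM in GDNF replicate 3. NEAT1 was lowest in these 2 libraries, at 65.7 and 54.0 CPM, though CT replicate 2 (67.6 CPM) and GDNF replicate 4 (66.7 CPM) lay close. That explanation stays open, since the interval in CT replicate 3 spans the bound set against it and neither interval lies wholly below the bound set for it. The 2 libraries carry the same replicate number, and the labels do not say what a number marks. No other biological explanation was tested, since the 2 libraries belong to different groups.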
